A study of Mus musculus with 11 samples.

How the data were processed

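Liver RNA of 6 Atg5-deficient and 5 wild-type libraries was profiled by RNA-seq after 5 weeks of CCl4. The design text of the series says that cells were sorted by flow cytometry, whereas the labels' protocols describe RNA from sections of formalin-fixed, paraffin-embedded blocks and a stranded total RNA kit. The labels alone do not settle which applies to these libraries, and for that reason markers of other liver cell types were measured in each. The deposited table holds raw counts of reads per Ensembl gene, 1 column per library. Reads were processed with STAR and featureCounts on GRCm38, per the submitters' processing notes, which give no versions. The annotation release, the strand setting and the handling of multimapping and duplicate reads are not given in the sources used here. Rpl13a and the overlapping Gm45713 had 776799 and 773696 counts, so reads over both genes were counted for both. Some genes on the other strand had few counts despite long overlaps. Fam69a shares 953 bases with Rpl5 and had 2.37% of its count, and Mrnip 580 bases with Sqstm1 (0.847%). A further gene shares 570 bases with Gabarapl1 (0.533%). Unless few reads fall on the shared bases, this argues against counting of both strands for those pairs. Other partners had more, such as Hoxaas3 with 46.15% of the Hoxa7 count, and could hold reads of their own. For such pairs, without the strand setting, the reads of the overlapping genes cannot be told apart.

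Gene IDs were matched to GENCODE M21 (GRCm38), from which symbols and coordinates were taken. Of 56748 IDs, 52073 (91.8%) matched, and they held 89.3% to 96.5% of the reads of a library. IDs without a match were tested but not named, and 19 of them were among the called genes. The table had 0 columns of other samples.

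Totals ran from 30699408 to 47564440 counts, so that 3 counts in a library correspond to 0.0631 to 0.0977 CPM, the level under which a gene cannot be told from absent. The common biological coefficient of variation was 0.341. Genotypes come from the labels, and replicates were numbered within a group in accession order, so numbers pair nothing. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM factors, and genotype was tested with edgeR's quasi-likelihood F test (robust) with Benjamini-Hochberg adjustment and a threshold of 0.05 over 17987 genes. CPM values of genes are TMM-scaled; summed markers of a cell type and counts of Gh use total counts. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

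Before the data were examined, 25 pathway lists and 14 cell type marker lists were fixed, along with the tests, the alternatives and the rule for naming genes. The lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a family with at least 3 tested members. Camera was repeated with an estimated correlation, and fry was run beside it. Of 21 pathway lists that passed by camera, 0 passed with an estimated correlation (8 lists at an unadjusted p under 0.05, and a smallest adjusted p of 0.149) and 18 passed by fry, which does not compare a list with other genes. Of 12 cell type lists tested, 4 passed by camera, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 1 by fry. Markers of CD8 T cells and neutrophils had fewer than 3 tested members and were only summed. Library properties, summed markers and list means were compared by exact permutation over all 462 splits of 6 and 5 libraries, two-sided, with 0.00216 as the smallest possible p.

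Genes named are Atg5, the 12 with the largest log2 fold change in each direction among called genes whose groups did not overlap, up to 4 members per list with the smallest p, and Il17a, Il17f, Il22, Il23r, Csf2, Ifng, Tbx21, Gata3, Foxp3, Cd4 and Sqstm1 always. Predicted genes, receptor segments, symbols that end in -ps and ribosomal RNA were counted but not named under that rule, which left Rps4l and Zscan30, annotated as transcribed processed pseudogenes, among those named. Not every gene that the rule covers is named.

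The test was checked on simulated counts drawn from the means and library sizes of these samples, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. It recovered 28.4%, 49.3% and 68.2% of them over 18100 genes, with 3 false calls of 100. Each gene was drawn independently, so the simulation lacks differences shared by many genes of a library. Its share of false calls need not hold for the real libraries. Alternatives were relative log expression and upper-quartile scaling, DESeq2, limma-voom with sample quality weights, no and a strict low-count filter, a library size without mitochondrial, haemoglobin and hepatocyte genes, an other-cell component or a surrogate variable as a covariate, libraries 75106 to 75113 alone, and each library left out in turn. Added after the data were seen were the side of the first principal component as a covariate, the samples on each side alone, and the permutation of list means.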

Results

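RNA was sequenced from the livers of mice injected with carbon tetrachloride (CCl4) for 5 weeks, a treatment that injures hepatocytes and leads to fibrosis. The series describes CD4 T cells sorted by flow cytometry, whereas the protocols of the labels describe sections of fixed, paraffin-embedded blocks. In every library the markers of CD4 T cells (6149 to 7856 CPM, counts relative to library size) summed above those of hepatocytes (207 to 2288 CPM), the main cells of liver tissue, so the libraries are not of whole liver sections. The labels do not settle how the cells were preserved. Of the 11 libraries, 6 came from mice whose T lymphocytes lack Atg5, a protein that autophagosomes need to form (Atg5-deficient), and 5 from mice with the undeleted floxed gene (wild-type). Libraries held 30699408 to 47564440 counted reads, and 41446 of 56748 genes had at least 1 read. The labels do not say that libraries came from separate mice, so p-values measure only the spread between these samples. Pairs of libraries within a group differed by 12.9 to 165 times the sampling noise (chi-square per degree of freedom). Total count, number of detected genes, share of the 20 most counted genes and mitochondrial share did not differ past the threshold between genotypes (adjusted p = 0.797 for each, exact permutation tests over all splits of the libraries, two-sided).

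The comparison asks how loss of autophagy alters liver CD4 T cells during fibrosis, and the series title names type 3 inflammation. Atg5 itself (ENSMUSG00000038160, chromosome 10, 44268358 to 44364291, plus strand, GRCm38) was counted at 19.2 ± 2.51 CPM in Atg5-deficient (SD, n = 6) and 16.9 ± 3.59 CPM in wild-type libraries (SD, n = 5). Its log2 fold change was 0.18 (SE 0.14, adjusted p = 0.488), and the single libraries spanned 15.2 to 22.5 and 13.4 to 21.1 CPM. Reads from exons outside the deleted part are counted for the gene too, and the deleted part is not given in the sources used here, so Atg5 at the gene level does not check the genotype labels. Cd4, the marker of the cells that the series describes, stood at 827 ± 145 CPM against 668 ± 35.8 CPM and did not pass the test (log2 fold change 0.31, SE 0.12, adjusted p = 0.122). Growth hormone (Gh, ENSMUSG00000020713, chromosome 11, 106300271 to 106301865, minus strand) rose most of the named genes. It had 271 to 953 counts in each Atg5-deficient library, 2954 in all, and 2 counts over the 5 wild-type libraries, of which 3 had 0. The ratio of the summed counts per read was 1270 (95% exact interval 350 to 10500, which covers counting error only).

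**Figure D1:**
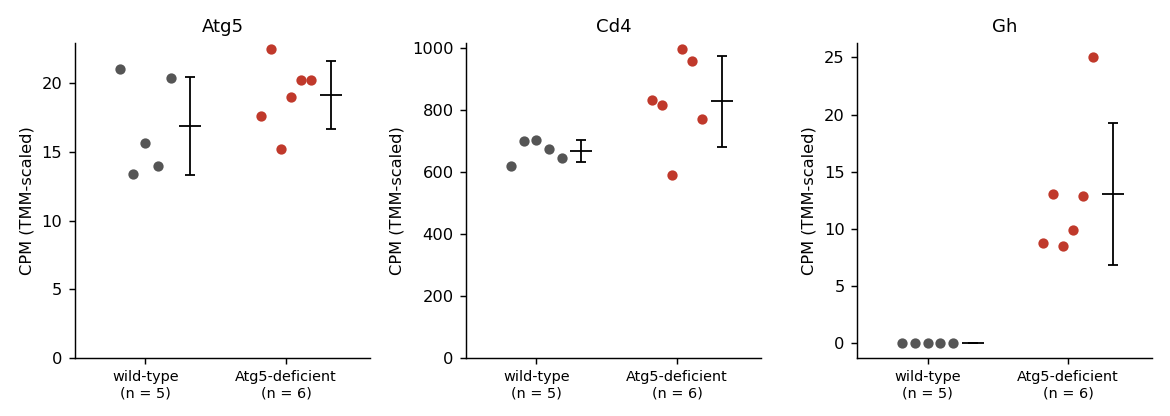
CPM (scaled by TMM factors) of Atg5, Cd4 and Gh in each library, with the mean and SD of each group beside the points. Atg5 overlaps between genotypes at 15.2 to 21.1 CPM, whereas Gh lies at 8.52 to 25.02 CPM in the 6 Atg5-deficient libraries and at no more than 0.0323 CPM in the wild-type libraries.

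Loss of Atg5 went with 797 higher and 434 lower genes among 17987 tested (edgeR, adjusted p under 0.05). After Gh, the largest rises were in Gzma, a granzyme of cytotoxic granules (log2 fold change 3.65, SE 0.85, adjusted p = 0.0328), Nccrp1 (3.02, SE 0.71) and Cx3cr1, the fractalkine receptor (2.95, SE 0.73). Gzma stood at 14.7 ± 17.3 CPM in Atg5-deficient and 1.19 ± 0.763 CPM in wild-type libraries, and Cx3cr1 at 12.8 ± 16.6 against 1.65 ± 0.477 CPM. Without Atg5-deficient replicate 1, which had 48.6 and 46.2 CPM, these means were 7.96 CPM for Gzma and 6.155 CPM for Cx3cr1, and the log2 fold changes 2.75 and 1.90. Sncb, Rps4l, Rtkn2, Il18, Psrc1, Smpdl3b, Apobec2 and Plek rose by log2 values of 1.74 (Plek) to 2.39 (Sncb). The largest falls were in the Ly49 receptor genes Klra1 (-3.06, SE 0.78) and Klra7 (-2.75, SE 0.76), the glutamate receptor gene Grm6 (-2.97, SE 0.55) and the homeobox gene Hoxa7 (-2.92, SE 0.59). Ptk2, the focal adhesion kinase, fell from 10.3 ± 1.69 to 3.06 ± 1.76 CPM (log2 fold change -1.76, SE 0.31, adjusted p = 0.00729). Kcnj16, Styk1, Cd55b, Scg5, Snord89, Hotairm1 and Zscan30 fell by log2 values from -1.65 (Zscan30) to -2.39 (Kcnj16). The groups did not overlap in 649 of the 1231 called genes and in 4.86% of all tested genes, where chance gives 0.433%. Klra1, Klra7, Rps4l and Cd55b have close paralogs with which reads could be shared, and Hoxa7 and Hotairm1 overlap genes on the other strand.

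The size of that list depended on single libraries and on the scaling. It came to 715, 642, 2143 and 702 genes without Atg5-deficient replicates 1, 2, 3 and 4, and to 673, 710 and 651 without wild-type replicates 1, 4 and 5. A core of 353 higher and 130 lower genes passed in all 11 fits that left out 1 library, Gh, Rps4l, Psrc1, Smpdl3b, Apobec2, Plek, Grm6, Hoxa7, Kcnj16, Styk1, Scg5, Ptk2 and Zscan30 among them. Il18 passed in 10 of those fits, Snord89 in 8, Rtkn2 in 7, Gzma in 6, Cx3cr1 in 5, Nccrp1, Klra1 and Cd55b in 4, Klra7 in 3 and Sncb and Hotairm1 in 1. Upper-quartile scaling gave 584 higher and 685 lower genes (46.0% higher, against 64.7%). Among the 8 libraries with consecutive numbers in their titles (5 Atg5-deficient, 3 wild-type) 176 genes passed.

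**Figure D2:**
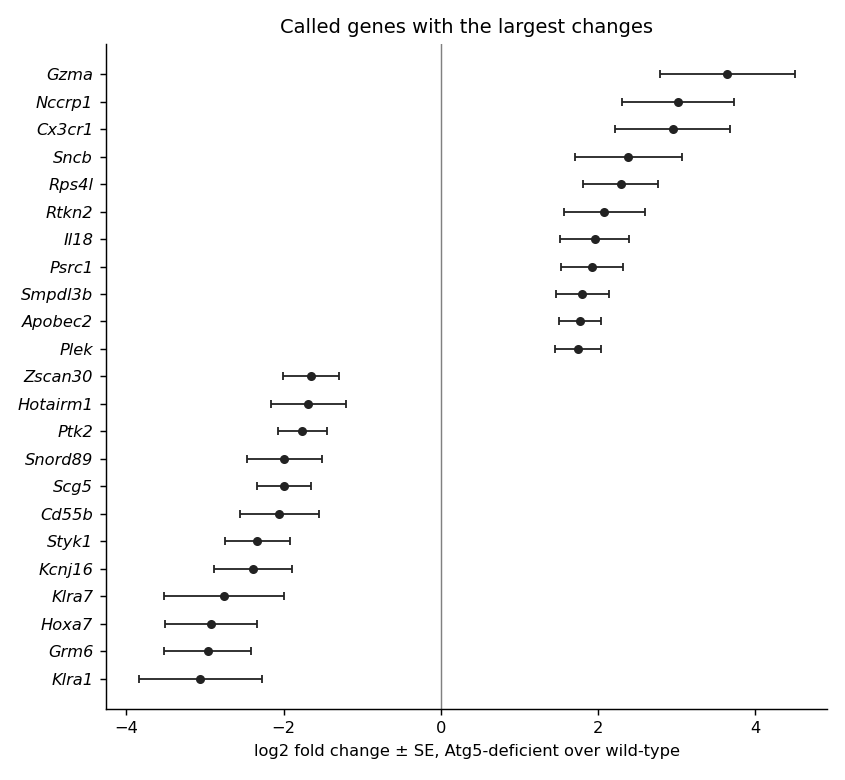
Log2 fold change and SE, Atg5-deficient over wild-type, of the genes with the largest called changes whose groups did not overlap; Gh is left out because its wild-type libraries held 2 counts. Values run from -3.06 (Klra1) to 3.65 (Gzma). Klra1 averaged 0.0622 CPM in Atg5-deficient libraries, under the level of 3 counts. Hoxa7 in Atg5-deficient libraries (0.0837 CPM) and Nccrp1 and Sncb in wild-type libraries (0.0888 and 0.0860 CPM) lay within that level.

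Genes of the type 3 (Th17) programme had positive log2 fold changes in 22 of 24 tested members, but the cytokine genes named here did not pass. Il18r1, the receptor chain for IL-18, rose from 144 ± 14.0 to 212 ± 21.5 CPM (log2 fold change 0.56, SE 0.09, adjusted p = 0.00505). The transcription factor genes Rora (0.89, SE 0.15) and Ahr (0.70, SE 0.13), which take part in Th17 differentiation, rose as well, and Il6st, the shared signalling chain of the IL-6 receptor family, fell (-0.55, SE 0.12). These 4 calls held in all 11 fits that left out 1 library. Il18r1 is also a member of the type 1 list and Ahr of the tissue residency list, so their rises are not particular to the type 3 programme. The cytokine genes had log2 fold changes of 0.75 for Il17a (adjusted p = 0.626), 0.48 for Il17f (adjusted p = 0.665), 1.67 for Il22 (adjusted p = 0.327) and 1.28 for Csf2 (adjusted p = 0.365), with 0.55 for Il23r (adjusted p = 0.618). Without wild-type replicate 3 the log2 fold changes were 1.71 for Il17a, 1.17 for Il17f and 1.06 for Il23r. The lowest were 0.41 for Il17a and 0.35 for Il23r without Atg5-deficient replicate 2, and 0.22 for Il17f without Atg5-deficient replicate 5, in each case without a call. The Atg5-deficient mean of Il22 was 0.647 CPM, and 0.321 CPM without replicate 2, which had 2.27 CPM. The wild-type mean was 0.203 CPM. Il17a ranged from 0.159 to 10.5 CPM among Atg5-deficient and from 0.903 to 8.87 CPM among wild-type libraries. Of 24 tested members 6 rose, 1 fell and 17 did not pass, and 9 and 2 passed when adjusted over the list alone. The median log2 fold change was 0.55 (camera, adjusted p = 6.75e-04), with adjusted p = 0.197 with an estimated correlation. An exact permutation test of the list's mean per library, added after the data were seen, gave adjusted p = 0.157, and 2 of 6 Atg5-deficient libraries stood above every wild-type library.

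**Figure D3:**
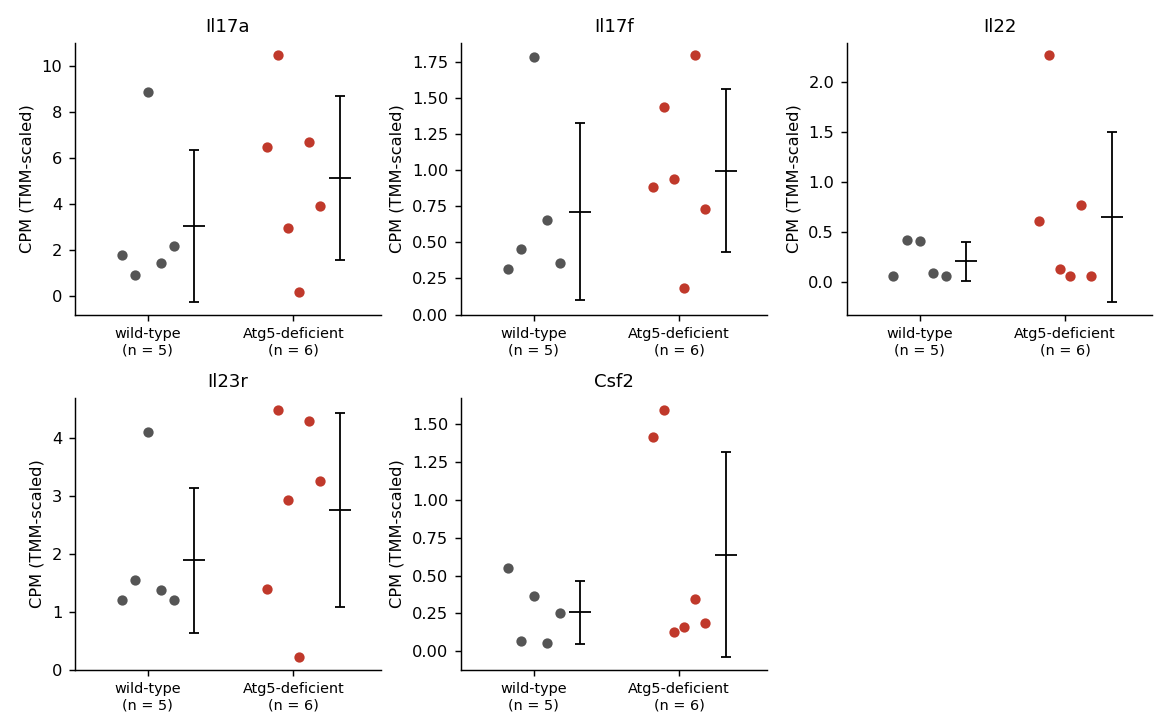
CPM of 5 genes of the type 3 programme in each library, with the mean and SD of each group beside the points. For all 5 genes the groups overlap, as for Il17a at 0.159 to 10.5 and 0.903 to 8.87 CPM.

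Type 1 and cytotoxic genes had positive log2 fold changes in 23 of 25 members. Tbx21, which encodes the lineage factor T-bet, went from 26.6 ± 6.64 to 59.1 ± 24.1 CPM (log2 fold change 1.15, SE 0.27, adjusted p = 0.0266), and passed in 7 of the 11 fits that left out 1 library. Il12rb1 (1.15, SE 0.19), a chain of the IL-12 receptor, the chemokine receptor gene Cxcr3 (1.04, SE 0.18) and Il18rap, the second chain of the IL-18 receptor, rose in all of those fits. Ifng stood at 39.2 ± 30.6 against 13.2 ± 4.68 CPM and missed the threshold (log2 fold change 1.57, adjusted p = 0.0913). It shares 336 exonic bases with another annotated gene, whose count was 103.7% of that of Ifng. Of 25 members 10 rose, none fell and 15 did not pass, 15 rising when adjusted over the list alone, and the median was 1.15 (camera, adjusted p = 5.94e-09). That call was lost with adjusted p = 0.149 with an estimated correlation. In the type 2 list Gata3 rose from 144 ± 16.6 to 199 ± 24.1 CPM (0.47, SE 0.10, adjusted p = 0.0157). Ccr4 (0.82) and Il1rl1 (0.85), the receptor for IL-33, rose too, though they passed in only 4 and 2 of the 11 fits. The other 8 of 11 members did not pass, the count adjusted over the list alone was also 3, and the median was 0.51 (camera, adjusted p = 0.00973), with adjusted p = 0.207 with an estimated correlation.

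Regulatory T cell genes had positive log2 fold changes in 18 of 19 members. Foxp3, the lineage factor (chromosome X, 7573644 to 7595245, GRCm38), went from 152 ± 29.1 to 266 ± 51.3 CPM (log2 fold change 0.81, SE 0.15, adjusted p = 0.00971), with all 6 Atg5-deficient libraries above every wild-type library. Ikzf2, which encodes Helios (0.77, SE 0.15), the integrin gene Itgae (1.29, SE 0.27) and Tnfrsf18, which encodes GITR (0.69, SE 0.16), rose as well. Without wild-type replicate 5 the call of Itgae was lost, and Tnfrsf18 passed in 8 of the 11 fits. Of 19 members 9 rose, none fell and 10 did not pass. Adjusted over the list alone 14 rose and 1 fell, and the median was 0.81 (camera, adjusted p = 5.42e-08), with adjusted p = 0.149 with an estimated correlation. The inhibitory receptor list shares Ikzf2, Tigit (0.97, SE 0.24) and Tox2 (0.73, SE 0.18) with other lists. It had 6 of 16 members higher, with Cd101 (0.44, SE 0.10), none lower, and 10 higher when adjusted over the list alone (median 0.82, camera, adjusted p = 1.08e-05), with adjusted p = 0.149 with an estimated correlation. Cd101 passed in 9, Tigit in 5 and Tox2 in 4 of the 11 fits. In the tissue residency list Prdm1, which encodes Blimp-1, rose from 42.5 ± 7.51 to 90.9 ± 29.3 CPM (1.10, SE 0.21), and 3 of 16 members rose with none lower, or 7 when adjusted over the list alone (median 0.68, camera, adjusted p = 1.49e-04), with adjusted p = 0.149 with an estimated correlation. Its other called members, Itgae and Ahr, are also in the regulatory and the type 3 list. Among follicular helper genes Icos rose from 81.8 ± 11.4 to 128 ± 16.6 CPM (0.65, SE 0.11). In all 2 of 12 rose, or 5 when adjusted over the list alone (median 0.49, camera, adjusted p = 0.0134), with adjusted p = 0.197 with an estimated correlation. The other called member was Tox2, also in the inhibitory receptor list.

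Genes of naive and central memory T cells moved the other way. Tcf7, which encodes the factor TCF-1, fell from 1412 ± 130 to 955 ± 180 CPM (log2 fold change -0.56, SE 0.12, adjusted p = 0.0148). Dapl1 (-1.13, SE 0.21), Actn1 (-0.84, SE 0.16) and Nsg2 (-0.74, SE 0.16) fell, as did Ccr7, the lymph node homing receptor gene (-0.72, SE 0.16). Without wild-type replicate 5 the calls of Nsg2 and Ccr7 were lost. Of 18 members 9 fell, none rose and 9 did not pass, or 12 lower when adjusted over the list alone, and the median was -0.58 (camera, adjusted p = 5.94e-09). The adjusted p was 0.197 with an estimated correlation. In the chemokine receptor list Ccr2, which guides cells into inflamed tissue, rose from 46.7 ± 6.72 to 98.0 ± 23.3 CPM (1.07, SE 0.16, adjusted p = 0.00380). With Cxcr3, Cx3cr1, Ccr4 and another receptor gene, 5 of 17 members rose and Ccr7 fell, or 7 and 1 when adjusted over the list alone (median 0.68, camera, adjusted p = 4.43e-04), with adjusted p = 0.149 with an estimated correlation.

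Cell cycle genes had positive log2 fold changes in 25 of 25 members, but not in every library. The list mean of Atg5-deficient replicate 3 (3.47 on the log2 CPM scale) lay within the wild-type range of 3.394 to 4.003, and the other 5 Atg5-deficient libraries lay above it. Mki67, the proliferation marker, went from 148 ± 26.0 to 364 ± 106 CPM (log2 fold change 1.30, SE 0.22, adjusted p = 0.00792), and Cdk1 (1.31, SE 0.23), Aurkb (1.70, SE 0.31) and Tk1 (1.03, SE 0.18) rose with it. Of 25 members 14 rose, none fell and 11 did not pass, or 19 higher when adjusted over the list alone, and the median was 1.18 (camera, adjusted p = 3.65e-12). The adjusted p was 0.197 with an estimated correlation. Among genes of glycolysis, 17 of 19 had positive log2 fold changes, and those called higher included Slc2a3, a glucose transporter gene (0.56, SE 0.08, adjusted p = 0.00252), Pfkp (0.52, SE 0.10), Gapdh (0.66, SE 0.13) and Aldoa (0.63, SE 0.13). In that list 9 of 19 rose and 1 fell, or 15 and 1 when adjusted over the list alone (median 0.52, camera, adjusted p = 1.02e-07), with adjusted p = 0.149 with an estimated correlation. Apoptosis genes included Apaf1 (0.67, SE 0.12) and Pmaip1, which encodes Noxa (0.97, SE 0.18), and 7 of 21 rose with none lower, or 8 when adjusted over the list alone. The median of the apoptosis list was 0.23 (camera, adjusted p = 4.47e-04), with adjusted p = 0.149 with an estimated correlation.

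Genes of cytosolic ribosomal proteins had negative log2 fold changes in all but 1 of 52 members. Rps20 went from 500.4 ± 56.1 to 336 ± 17.1 CPM (log2 fold change -0.58, SE 0.08, adjusted p = 0.00306), Rpl5 from 1066 ± 129 to 745 ± 20.6 CPM (-0.52, SE 0.08), and Rps16 (-0.52, SE 0.08) and Rps29 (-0.71, SE 0.13) fell as well. Of 52 members 28 fell, none rose and 24 did not pass, or 39 lower when adjusted over the list alone. The median was -0.34 (camera, adjusted p = 2.06e-19), with adjusted p = 0.149 with an estimated correlation. All 6 Atg5-deficient libraries had a lower list mean than every wild-type library. The exact permutation of that mean, added after the data were seen, gave p = 0.00216, the smallest that the splits allow (adjusted p = 0.0216). Ribosomal protein genes have many processed pseudogenes, with which reads could be shared.

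**Figure D4:**
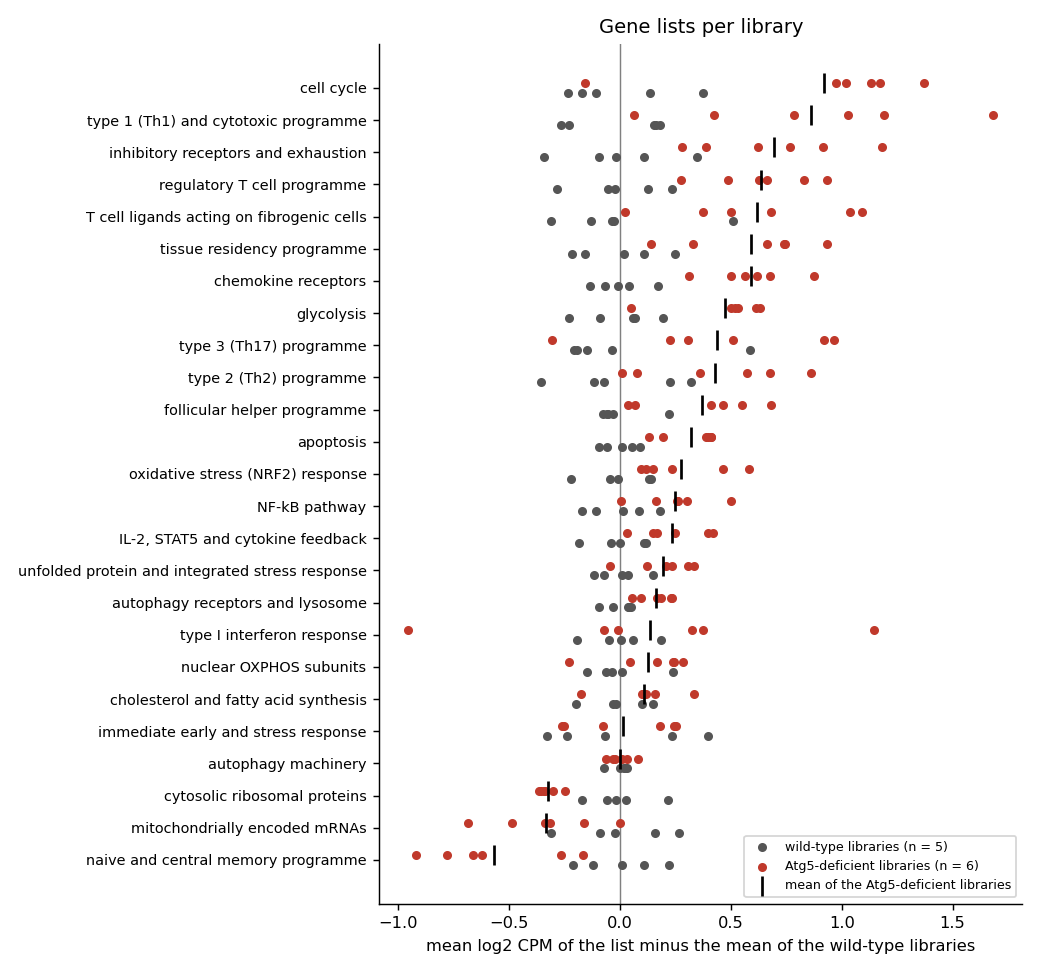
Mean log2 CPM of each of 25 gene lists in each library, relative to the mean of the 5 wild-type libraries; the black tick is the mean of the 6 Atg5-deficient libraries. The cell cycle list differs most (0.92) and the naive and central memory list lies lowest (-0.57), while the autophagy machinery list stays at 0.00135.

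Autophagy genes were measured in a list of the machinery and a list of receptors and the lysosome. Of 34 genes of the machinery, Atg5 among them, Gabarapl1, an LC3 family member (log2 fold change 0.70, SE 0.20, adjusted p = 0.0462), and Atg4d (0.38, SE 0.11, adjusted p = 0.0491) rose, and 32 did not pass. With edgeR 0 passed when adjusted over the list alone, 4 higher and 3 lower genes had an unadjusted p under 0.05, DESeq2 called 3 higher genes, and limma-voom called 4 higher and 2 lower. The calls of Gabarapl1 and Atg4d each held in 3 of the 11 fits. Atg4d overlaps a more highly counted gene on the other strand. The median was 0.02 (camera, adjusted p = 0.594), and -0.05 with upper-quartile factors. The receptor gene Sqstm1 stood at 225 ± 29.3 against 190 ± 19.4 CPM (0.24, SE 0.10, adjusted p = 0.167). Among 29 genes of autophagy receptors and the lysosome, Lamp2 (0.51, SE 0.10), Optn (1.27, SE 0.32) and Tfe3 (0.35, SE 0.10) rose and the sialidase gene Neu1 fell (-0.42, SE 0.09). Optn and Tfe3 passed in 4 and 2 of the 11 fits. With 6 higher and 2 lower when adjusted over the list alone, the median was 0.17 (camera, adjusted p = 0.0200), with adjusted p = 0.197 with an estimated correlation.

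Ligands by which T cells act on fibrogenic cells were also measured. Tnf rose from 20.1 ± 1.79 to 29.8 ± 4.47 CPM (log2 fold change 0.57, SE 0.11, adjusted p = 0.00996), and Csf1 (1.46, SE 0.35), Tnfsf11, which encodes RANKL (0.62, SE 0.16), and Tgfb3 (1.07, SE 0.29) rose with it, though these passed in 5, 3 and 4 of the 11 fits. Of 21 ligands 4 rose and 17 did not pass, or 6 higher when adjusted over the list alone (median 0.75, camera, adjusted p = 1.51e-04), with adjusted p = 0.176 with an estimated correlation. In the NF-kB list Nfkb2 (0.63, SE 0.17) and Icam1 (0.63, SE 0.15) were among 4 of 20 higher genes, 5 when adjusted over the list alone (median 0.24, camera, adjusted p = 6.75e-04), with adjusted p = 0.207 with an estimated correlation. Il2rb (0.69, SE 0.14), Cish (0.56, SE 0.14) and Socs2 (1.09, SE 0.27) rose among 17 genes of IL-2 and STAT5 signalling, with 7 higher and 1 lower when adjusted over the list alone (median 0.27, camera, adjusted p = 0.0167), and adjusted p = 0.238 with an estimated correlation. Of these, Nfkb2 passed in 4, Icam1 in 5, Cish in 6 and Socs2 in 7 of the 11 fits.

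RNA of other cell types was present in every library. Of 10 tested genes of NK, NKT and gamma-delta T cells, 9 had negative and 1 a positive log2 fold change, the latter at an unadjusted p under 0.05. Klra1 and Klra7 were called lower, with 8 not past, and 7 lower when adjusted over the list alone. Their median was -1.44 (camera, adjusted p = 4.08e-04), with adjusted p = 0.119 with an estimated correlation. Klrb1c, which encodes NK1.1, stood at 1.997 ± 1.30 against 5.58 ± 2.45 CPM (-1.49, adjusted p = 0.0724). The summed markers of that list came to 14.95 ± 4.56 CPM in Atg5-deficient (SD, n = 6) and 28.3 ± 5.63 CPM in wild-type libraries (SD, n = 5; exact permutation p = 0.00649, adjusted over 14 cell types p = 0.0909). Hepatocyte markers were positive in 30 of 30 genes (median 0.81, camera, adjusted p = 0.0247; adjusted p = 0.960 with an estimated correlation), with 1 called, Ass1 (0.64, SE 0.13), also when adjusted over the list alone. They summed to 207 to 2288 CPM in the single libraries, 1275 ± 891 against 706 ± 467 CPM (exact permutation p = 0.229, n = 6 and 5). So the hepatocyte list passed camera, but neither the estimated correlation nor the permutation of its sum, and among the 8 libraries with consecutive numbers the direction of its test turned (median 0.351, adjusted p = 0.729). In Atg5-deficient replicate 5 the hepatocyte sum was only 516 CPM, but Ass1 stood at 243 CPM, above its group mean of 170 CPM. The call of Ass1 thus does not by itself show hepatocyte RNA. In the dendritic cell list Cd74 (0.88, SE 0.16) and Itgax (2.67, SE 0.66) rose of 7 tested members, 3 when adjusted over the list alone (median 0.59, camera, adjusted p = 0.0247), with adjusted p = 0.609 with an estimated correlation. Itgax passed in 5 of the 11 fits that left out 1 library. B cell genes had a median of 0.48 (camera, adjusted p = 0.0364; adjusted p = 0.960 with an estimated correlation). Of its 12 members edgeR called 0, also when adjusted over the list alone, with 2 higher at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Markers of CD4 T cells summed to 7096 ± 668 against 6917 ± 547 CPM (exact permutation p = 0.630, n = 6 and 5). Among 18 of them Cd5 (0.40, SE 0.09) and Zap70 (0.35, SE 0.10) rose and Tcf7 fell, or 3 and 1 when adjusted over the list alone (median 0.11, camera, adjusted p = 0.509). Cd5 passed in 9 and Zap70 in 4 of the 11 fits. The hepatocyte call was lost without any 1 of Atg5-deficient replicates 1, 2 and 3 and wild-type replicates 1 and 5, with medians of 0.51 to 0.69.

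**Figure D5:**
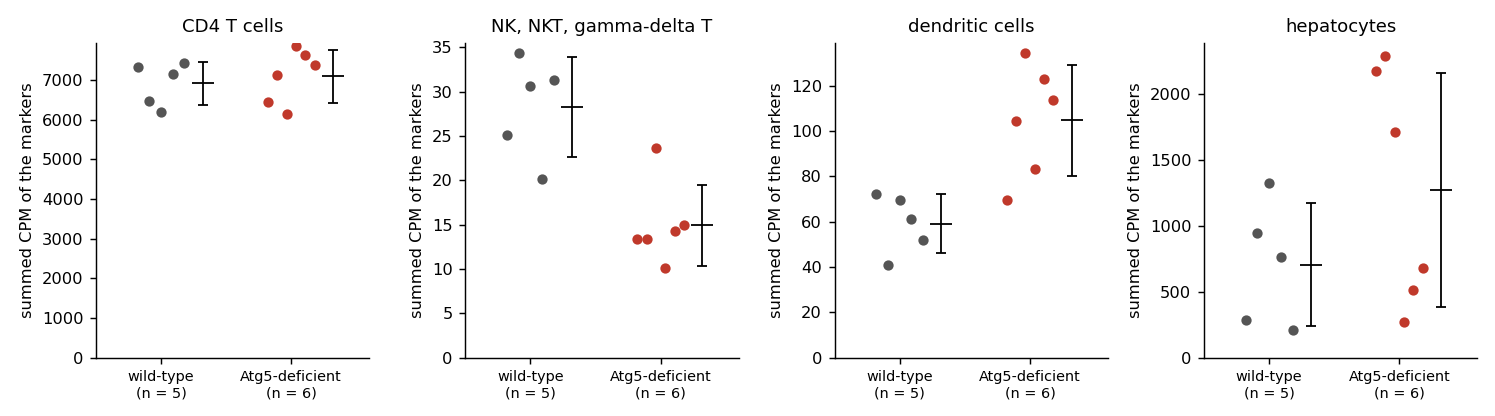
Summed CPM of the marker genes of 4 cell types in each library, with the mean and SD of each group beside the points. CD4 T cell markers lie between 6149 and 7856 CPM, hepatocyte markers between 207 and 2288 CPM.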

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

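Within the 2 genotypes, 290 groups of values were searched for a library far from the rest, and 18 had one, where chance gives about 1 in 20. Tests on the growth hormone segment and on the excess of pituitary hormones were chosen after the results were seen, and the other tests of this part before.

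Atg5-deficient replicate 3 stood apart most often. Its cell cycle list averaged 3.47 on the log2 CPM scale (others 4.60 to 5.00), with Mki67 at 168 CPM (others 332.0 to 462.4) and Aurkb at 2.48 CPM (others 6.93 to 11.3). Its list of NK, NKT and gamma-delta T cell genes was high at 0.271 (others -1.15 to -0.684), and Neu1 was low at 32.3 CPM (others 38.9 to 41.8). Wild-type replicate 3 had the highest wild-type mean of the type 3 list, 4.22 (others 3.43 to 3.60), and of the follicular helper list, 4.37 (others 4.07 to 4.12), with Il23r at 4.10 CPM (others 1.20 to 1.55). In Atg5-deficient replicate 4 Il17a was at 0.159 CPM (others 2.96 to 10.5). Atg5-deficient replicate 6 was low in the glycolysis list, 6.06 (others 6.51 to 6.64), and in Aldoa, 257 CPM (others 362 to 418). Rtkn2 was low in Atg5-deficient replicate 2 (0.430 CPM, others 0.822 to 1.13), Grm6 in wild-type replicate 2 (0.871 CPM, others 1.97 to 2.48) and Ccr4 in wild-type replicate 1 (22.6 CPM, others 28.7 to 30.3). Tnf was high in Atg5-deficient replicate 1 (38.8 CPM, others 26.9 to 29.7). More genes were detected in wild-type replicate 3 (30811, others 25366 to 26582) and in Atg5-deficient replicate 2 (33192, others 23962 to 26085). The 20 most counted genes took 28.0% of the reads of Atg5-deficient replicate 1 (others 21.5% to 23.7%).

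Growth hormone reads appeared in all 6 Atg5-deficient libraries at 8.32 to 26.1 CPM of total counts, and came to 2 counts over the wild-type libraries. Against RNA from pituitary tissue, the other abundant pituitary hormones Prl, Pomc and Cga came to 5.579% of the Gh level, between the bounds of 1% and 10% set beforehand, but Prl had 0 counts and Pomc had 161 counts in Atg5-deficient and 167 in wild-type libraries. Taken as an excess over wild-type libraries, these hormones came to -1.146% of the Gh level, which argues against pituitary RNA. A growth hormone segment within the Cre transgene, a part of some such constructs, is a candidate source, since 6 of 6 Atg5-deficient libraries lay above every wild-type library. That count is the pattern itself and the construct and the reads were not used here, so this source and expression of the gene cannot be told apart.

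The fall of ribosomal protein genes was weighed against gene length, scaling and other cells. After removal of the length and GC trend of the other genes the median of the list was -0.3325, from -0.345, all 52 members having a length. Its SE of 0.0273 was taken over the 52 genes as if independent, and leaves out the spread between libraries. Over the other scalings the median reached at most -0.3412, and with the other-cell component as a covariate it was -0.3567. So length, GC, scaling and that component do not account for the fall as a whole. The component pools the markers of all cell types other than CD4 T cells, so single cell types were not tested. Reads shared with processed pseudogenes and the quality of RNA were not tested. A difference between the genotypes, or a shift from resting to cycling cells within them, may also lie behind it and was not tested.

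The rise of type 1, regulatory and cell cycle genes was weighed against RNA of other liver cells and against libraries numbered far from the rest. With the other-cell component as a covariate the smallest of the 3 ratios of list medians to those without it was 0.9602. Among the 8 libraries with consecutive numbers the smallest ratio was 0.9499, although 176 genes passed there with fewer samples. The first ratio argues against RNA tracked by that component, which pools the markers of all cell types other than CD4 T cells. It does not decide on single cell types, which were not used as covariates. The second ratio argues against the libraries numbered far from the rest as the only source of the rise. It does not decide on library number itself. The 8 libraries are part of the full set, and the lowest numbers among them are wild-type. The genotype and the mix of CD4 T cell subsets in the libraries stay open, since no measure of single cells was used here.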

How the results depend on the processing

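Settings on the sides of the first principal component (side A holds Atg5-deficient replicates 1, 2 and 3 and wild-type replicates 2 and 3, side B the others) and the permutation of list means were chosen after seeing the data. Every called gene that could be tested kept its sign in each alternative fit, and Atg5 stayed without a call (log2 fold change 0.11 to 0.40). Called genes came to 2333 with DESeq2 (1394 higher, 939 lower), 3426 with limma-voom (1966 higher, 1460 lower), 1269 with upper-quartile factors (685 lower), 176 among the 8 libraries with consecutive numbers (87 higher, 89 lower) and 488 on side A (74 higher), the last pair with fewer samples. Side B gave 1058, and the other scalings, filters and covariates gave 1258 to 1478. Leaving out 1 library gave 642 to 2143 genes (402 to 1410 higher, 191 to 733 lower), with 715, 642, 2143 and 702 without Atg5-deficient replicates 1, 2, 3 and 4, 673, 710 and 651 without wild-type replicates 1, 4 and 5, and 276 lower without wild-type replicate 3. Pathway lists past the threshold went from 21 to 0 with an estimated correlation (8 at an unadjusted p under 0.05, 18 by fry) and 13 by permutation of list means, and lay between 17 and 22 otherwise. By that permutation the type 2 (adjusted p = 0.0769), OXPHOS (0.303), mitochondrial mRNA (0.0691) and NRF2 lists (0.0541) lost their calls. So did the NF-kB, follicular helper and unfolded protein lists (adjusted p = 0.0507 for each). The type 3 list lost its call with an estimated correlation (median 0.5543) and by permutation (mean difference 0.4355), and passed in every other setting run (median 0.36 to 0.78). Cell type lists went from 4 to 2 with limma-voom and on side A, 1 by fry, and 0 with a strict filter, with an estimated correlation and by permutation. They went to 1 to 4 with a library left out (1 without Atg5-deficient replicate 3 or wild-type replicate 5, 2 without wild-type replicate 2). Directions of a test turned on side A for Il17f (-0.0353), immediate early genes (0.133), OXPHOS (-0.0233), interferon (-0.245, adjusted p = 0.0495 by camera), stellate (0.398) and erythroid lists (0.866). They turned on side B for autophagy machinery (0.00885) and plasma cells (-0.202), and with upper-quartile factors for autophagy machinery (-0.0480) and stellate cells (-0.0216). With limma-voom they turned for immediate early genes (0.0754), plasma (-0.880) and stellate cells (0.0913), without a low-count filter for immediate early genes (0.0389) and stellate cells (0.141), and by permutation for immediate early genes (0.0139). With a surrogate variable they turned for plasma (0.959), macrophages (-0.0838) and endothelium (0.0214), and among consecutively numbered libraries for macrophages (0.130), hepatocytes (0.351), endothelium (-0.0915) and erythroid cells (0.815). With a library left out, lists that turned spanned 0.0118 to 0.1175 (immediate early), -0.0522 to 0.470 (interferon), -0.0247 to 0.849 (plasma), -0.0751 to 0.512 (macrophages), 0.114 to 0.754 (endothelium), -0.107 to 0.4085 (stellate) and -0.157 to 0.231 (platelets and mast cells). Of all these only OXPHOS and hepatocytes had a call over all libraries. Beyond the smaller numbers of samples named, the cause was not tested. Genes under 0.0631 to 0.0977 CPM lay below 3 counts.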

Other observations

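In this part the tests of splits, of the level of Trav11 and of the diversity of Trbv segments were chosen before their results were seen. Those on side A and on the mean of the type 3 list were not. Several further gene groups were also measured. Interferon response genes had a median log2 fold change of 0.31 with wide spread among Atg5-deficient libraries (camera, adjusted p = 0.210; adjusted p = 0.774 with an estimated correlation). The list mean was 3.76 in Atg5-deficient replicate 3 and 5.86 in replicate 5, against 4.52 to 4.90 in wild-type libraries, and without replicate 3 the list passed camera (median 0.47, adjusted p = 0.00204). Isg15 stood at 12.6 ± 6.37 against 7.98 ± 1.98 CPM (edgeR, adjusted p = 0.287). Of 21 members edgeR called 0, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by limma-voom. Jun, of the immediate early list, fell from 553 ± 77.5 to 391.8 ± 36.9 CPM (log2 fold change -0.50, SE 0.10, adjusted p = 0.0116). The other 24 members did not pass, 1 fell when adjusted over the list alone, and the median of 0.04 and mean of 0.07 had the opposite sign to the test (camera, adjusted p = 0.942).

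Nuclear OXPHOS subunits had 31 of 35 positive values and a median of 0.16 (camera, adjusted p = 0.00478; adjusted p = 0.540 with an estimated correlation; median -0.0233 on side A of the first principal component, a setting chosen after seeing the data), with Sdhb nearest to a call (0.30, SE 0.09, adjusted p = 0.0515). EdgeR called 0 of them, also when adjusted over the list alone, with 6 at an unadjusted p under 0.05, 1 called by DESeq2 and 11 by limma-voom. Mitochondrially encoded mRNAs had a median of -0.22 (camera, adjusted p = 0.0200; adjusted p = 0.353 with an estimated correlation), with mt-Nd2 at 182 ± 37.6 against 227 ± 18.2 CPM. Of 12 members edgeR called 0, also when adjusted over the list alone, with 4 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. Txnrd1 (0.56, SE 0.13) and Txn1 (0.65, SE 0.19), of the thioredoxin system, rose among 17 NRF2 response genes and passed in 9 and 3 of the 11 fits that left out 1 library, with 4 higher when adjusted over the list alone (median 0.23, camera, adjusted p = 9.86e-04; adjusted p = 0.207 with an estimated correlation). Atf6, a sensor of endoplasmic reticulum stress, rose from 36.6 ± 5.19 to 59.1 ± 8.49 CPM (0.69, SE 0.12, adjusted p = 0.00624). It was 1 of 21 genes of the unfolded protein response, also when adjusted over the list alone (median 0.16, camera, adjusted p = 0.0337; adjusted p = 0.414 with an estimated correlation). Scd2 (0.83, SE 0.19) was the 1 called of 20 cholesterol and fatty acid genes, also when adjusted over the list alone, and passed in 8 of the 11 fits (median 0.08, camera, adjusted p = 0.118; adjusted p = 0.543 with an estimated correlation).

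The remaining cell types did not differ past the threshold by camera (adjusted p = 0.759 to 0.942) or by their summed CPM (exact permutation p = 0.104 to 0.866). EdgeR called 0 of their members, with 2 macrophage and 2 cholangiocyte genes higher and 1 stellate gene lower at an unadjusted p under 0.05. DESeq2 called 1 macrophage gene, and limma-voom called 2 macrophage genes, 1 endothelial, 1 stellate and 1 platelet or mast cell gene. The medians of the stellate list (0.03) and of the platelet and mast cell list (0.12, with a mean of -0.02) had the opposite sign to the test. The sums in Atg5-deficient and wild-type libraries were 29.1 and 14.9 for plasma cells, 29.4 and 25.4 for macrophages, 164 and 187 for endothelial cells, 51.4 and 44.3 for stellate cells and fibroblasts, 41.0 and 15.6 for cholangiocytes, 7.41 and 8.08 for erythroid cells, and 5.27 and 6.61 for platelets and mast cells. CD8 T cell markers summed to 5.27 and 5.37 CPM and neutrophil markers to 2.44 and 1.29 CPM. Dendritic cell markers, whose list passed camera, summed to 105 and 59.1 CPM (exact permutation p = 0.0152, adjusted p = 0.106). The Y-linked gene Ddx3y lay between 67.9 and 114 CPM in all 11 libraries and Xist at no more than 0.391 CPM.

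Receptor segments were used to test a pair of hypotheses. No prediction was written beforehand for Zbtb16, Traj18, Trav entropy or the share of the most counted Trbv segment. None of their p-values, nor those of Trav11 and Trbv entropy, is adjusted. Fewer invariant NKT cells would lower Trav11, their receptor alpha segment. Its mean log2 CPM differed by -1.395 between Atg5-deficient and wild-type libraries (exact permutation p = 0.0216, n = 6 and 5), and Zbtb16, the factor of that lineage, stood at 2.67 ± 2.46 against 6.79 ± 1.48 CPM (exact permutation p = 0.0173). Zbtb16 is also a member of the NK, NKT and gamma-delta T cell list whose fall prompted the hypothesis, so it adds no separate support. The difference in Trav11 is what fewer such cells behind the Atg5-deficient libraries would give. However, Traj18 at 11.7 ± 3.38 against 14.3 ± 5.67 CPM did not differ past the threshold (exact permutation p = 0.344), and Trav11 lay at only 0.222 and 0.604 CPM.

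Clonal expansion in Atg5-deficient cells would lower the diversity of beta segments. The Shannon entropy over 28 Trbv segments differed by -0.1014 bits (3.96 ± 0.105 against 4.06 ± 0.0377, exact permutation p = 0.0455, n = 6 and 5), and that over 121 Trav segments by -0.1415 bits (p = 0.0195 in the same exact test). The share of the most counted Trbv segment, 16.65% against 13.15%, did not differ past the threshold (exact permutation p = 0.117). The differences in entropy are small and in line with somewhat more uneven segment use, but the share of the top segment does not show an expansion. Segment counts do not resolve clones, and a change in the mix of subsets may lower entropy as well.

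Chance was asked about with 100 splits of the 11 libraries into 6 and 5. For called genes 2 of 100 splits, the real one included, reached the real 1231, with 1336 as the highest other. That share is under 0.05, but without adjustment over the 4 questions asked of these splits, so chance is unlikely but not excluded. The split with 1336 genes set Atg5-deficient replicates 1, 2, 4 and 5 with wild-type replicate 2 against the remaining libraries. The median over other splits was 0. For the number of pathway lists that pass camera 3 of 100 splits reached the real 21, with 21 as the highest other, so chance is not excluded there either. The median over other splits was 7, so camera passed lists in splits that mix the genotypes too. With an estimated correlation 0 of the 21 passed (8 lists at an unadjusted p under 0.05, 18 by fry). For the type 3 list 4 of 100 splits reached the real median of 0.554, with 0.6996 as the highest other, but an exact permutation of its mean over all splits, a test chosen after seeing the data, gave p = 0.126, so chance stays open for this list. For cell type lists (37 of 100, real 4, highest other 8, median of other splits 3) chance cannot be excluded.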
